A study of Rattus norvegicus with 6 samples.

How the data were processed

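Total RNA was measured in 6 samples of neural stem cells from the adult rat hippocampus after 12 days of differentiation. Per the labels' protocols, RNA was isolated on columns, labelled with biotin by a 3' in vitro transcription kit and hybridised to Affymetrix expression arrays, which read each gene near its 3' end. The groups, stimulated and non-stimulated, and the replicate numbers 1 to 3 come from the sample titles. A treatment label states that no treatment preceded the isolation of RNA, which leaves the light schedule to the titles and source names.

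The value table deposited by the authors holds log2 signals of 31099 probe sets on 6 arrays. The submitters' processing notes name Affymetrix Expression Console, RMA and MAS5 without a role or version. The values lie between 2.25 and 14.1, and the SD of each group differs by at most 0.0056 from the SD in the workbook of the authors, whose header gives a log2 scale. A step that scales the arrays to a common distribution pulls array medians together and would hide a shift shared by most genes. The deposited workbook also holds, per the file headers, bi-weight averages of the log2 signals per group, a signed linear fold, an ANOVA p-value and an FDR p-value for 31042 probe sets. Its readme sheet says that gene lists past a fold of 1.5 were submitted to the annotation service DAVID. For each DAVID term the authors deposited the number of genes, a p-value, a Benjamini p-value and the fold enrichment as a ratio against a background that is not stated. All probe sets named in these terms had an ANOVA p under 0.05.

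No further normalization was applied. The 57 control probe sets were left out of every comparison and no filter was set on dim probe sets. Gene symbols come from the workbook, in which 21605 probe sets carry 1 symbol, 1270 carry several and 8167 carry none. Probe sets with several symbols or none entered the count of probe sets only. A gene was represented by its probe set with the highest mean over the 6 arrays, which gave 14605 genes, and for genes with values in the report, a probe set of the opposite sign is given with the value, as are some that differ in size. Of the symbols, 13174 are current in a table of rat genes on assembly GRCr8, 697 matched an older name there and 734 did not match or were ambiguous. That table served for names and for comparing the chromosomes of called genes, and coordinates are those of the workbook.

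Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, stimulated minus non-stimulated, no covariate), with Benjamini-Hochberg adjustment over all genes or probe sets tested and a threshold of 0.05. The residual degrees of freedom were 4 and the prior degrees of freedom 3.98. Depth has no meaning for arrays, and their number, 3 per group, sets the precision. In 20 simulations of 14605 genes with 200 changed genes for the same 3 against 3 comparison, 75% of genes changed 2-fold and 97.4% of genes changed 4-fold were recovered, and 5.08% and 5.10% of the calls were false. The recovered shares hold for 200 changed genes with independent noise, whereas 8 genes passed in the data. The adjusted threshold is stricter when fewer genes change, so these shares do not estimate how many changed genes were found here. With no change simulated, the highest count was 0 genes and 0 lists. A list shifted by 0.3 on the log2 scale was called in all 20 simulations, but simulated genes varied independently, which members of real lists do not.

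The 22 gene lists, written before the data were examined, were tested two-sided with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the members of a list on balance move one way without comparing them with other genes, were alternatives. Gene loadings of the first component were tested with limma's cameraPR at both kinds of correlation. The genes named in the text follow a rule set at the same time. It takes up to 12 genes per direction with the largest fold among those past the threshold whose groups do not overlap, in each list up to 4 members past the threshold or, if none passed, the 2 with the largest fold as values only, and 12 marker genes in every case. Some genes that this rule selects are not reported here. *Lef1* as a probe set call falls under the list rule, and other names were chosen after their values were seen and are marked so.

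Alternatives set beforehand were the replicate number as a block, quantile normalization, median centring, filters on dim probe sets, an intensity trend with robust moderation, array weights, other ways to choose a probe set per gene, the workbook of the authors, leaving out each array in turn, a plain test without moderation, a test against a fold of 1.5, and other thresholds. A pseudocount was not tried, since the values are already on a log scale. After the data were seen, 2 alternatives were added, one without stimulated replicate 3 and non-stimulated replicate 1 and one with the first component of the residuals as a covariate. All 10 splits of the 6 arrays into 3 and 3 were fitted as well. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.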

Results

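Gene expression was measured in neural stem cells from the adult rat hippocampus after 12 days in differentiation medium, with or without optogenetic stimulation. In optogenetics, cells carry a light-gated channel or pump, so that light changes their membrane potential. The labels form a stimulated group of 3 samples and a non-stimulated group of 3 samples, each hybridised to 1 rat expression array. The sample titles give a stimulation of 30 minutes, whereas another label describes stimulation throughout the 12 days, so the duration behind every value here is unsettled. Values are log2 signals per probe set, and the array medians lay between 5.95 and 6.01. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. The comparison asks which genes and gene groups differ in expression between stimulated and non-stimulated cells on day 12.

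Expression differed between the groups in 8 of 14605 genes, 7 of them higher and 1 lower in stimulated cells. *Hmox1*, which encodes the heme-degrading enzyme heme oxygenase 1, rose 3.35-fold, and *Frzb*, which encodes a secreted inhibitor of Wnt signalling, rose 2.74-fold. *Igfbp2*, a binding protein of insulin-like growth factors, rose 2.26-fold, and *Lgals1*, which encodes the carbohydrate-binding protein galectin-1, rose 2.03-fold. *Axl*, a receptor tyrosine kinase, rose 1.87-fold, and *Stat3*, a transcription factor downstream of cytokine receptors, rose 1.77-fold. *LOC100910286*, which was not found in the table of gene names, rose 1.93-fold. *Nptx1*, which encodes the secreted synaptic protein neuronal pentraxin 1, fell by 2.13 on the log2 scale and was 4.37-fold higher in non-stimulated cells. In each of these genes all 3 stimulated arrays lay on one side of all 3 non-stimulated arrays, which selection by p makes likely.

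Mean *Hmox1* signal was 9.09 ± 0.33 (SD, n = 3) in stimulated and 7.34 ± 0.11 (SD, n = 3) in non-stimulated cells, a log2 difference of 1.74 (SE 0.169, limma adjusted p = 0.0299). *Frzb* signal was 8.13 ± 0.036 against 6.68 ± 0.040, a difference of 1.46 (SE 0.0921, limma adjusted p = 0.00387), and its other probe set also passed, with a difference of 1.22. *Igfbp2* signal was 8.65 ± 0.16 against 7.47 ± 0.15, a difference of 1.18 (SE 0.127, limma adjusted p = 0.0366). *Lgals1* signal was 10.87 ± 0.081 against 9.85 ± 0.084, a difference of 1.02 (SE 0.101, limma adjusted p = 0.0299). *LOC100910286* signal was 6.0 ± 0.10 against 5.05 ± 0.12, a difference of 0.95 (SE 0.109, limma adjusted p = 0.0459), whereas its other probe set gave 0.35. *Axl* signal was 8.15 ± 0.027 against 7.25 ± 0.081, a difference of 0.90 (SE 0.0961, limma adjusted p = 0.0366). *Stat3* signal was 8.71 ± 0.077 against 7.88 ± 0.025, a difference of 0.83 (SE 0.0955, limma adjusted p = 0.0459), and its other probe set gave 0.71. *Nptx1* signal was 6.87 ± 0.12 against 9.00 ± 0.27, a difference of -2.13 (SE 0.152, limma adjusted p = 0.00487).

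**Figure D1:**
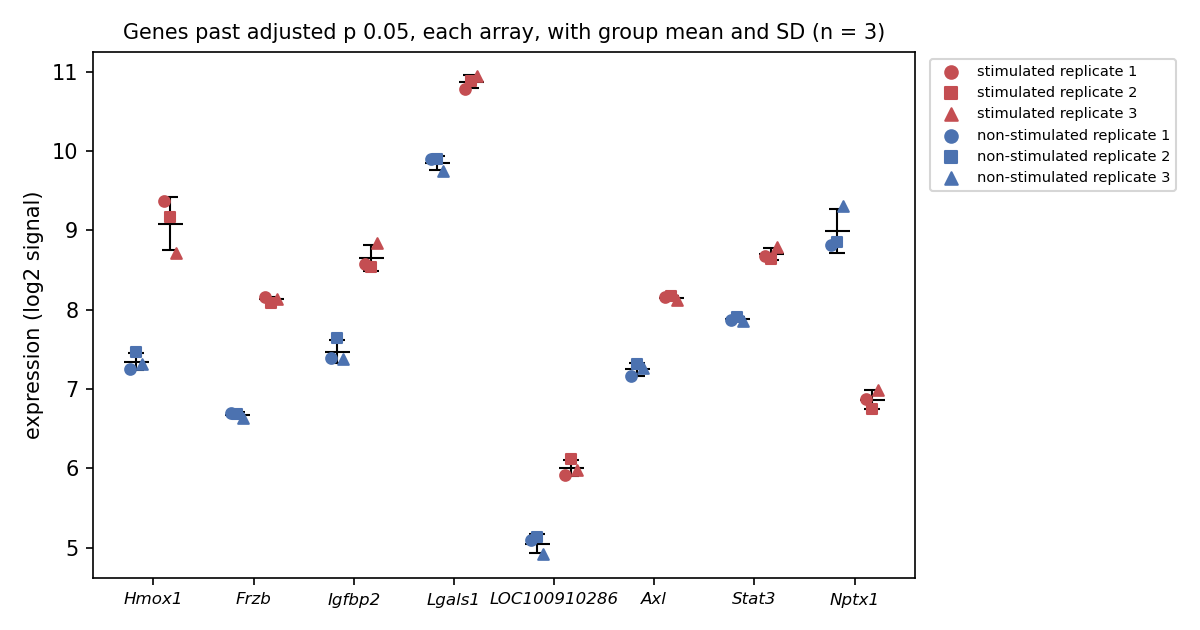
Log2 signal (vertical axis) of the 8 genes past adjusted p 0.05 in each array, with red points for stimulated and blue points for non-stimulated arrays, a marker shape per replicate number, and bars for the group mean and SD (n = 3). The stimulated arrays lie above the non-stimulated ones in 7 genes and below them in *Nptx1*, where the means are 6.87 and 9.00.

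All 8 genes differed by at least 1.5-fold, the smallest of them by 1.77-fold. An unadjusted p under 0.05 was reached by 940 genes, 536 higher and 404 lower, where 730 would be reached with no effect. The groups did not overlap in 10.7% of genes, and chance gives 10%. At the level of probe sets, 9 of 31042 passed, 8 higher and 1 lower. They included 1 of the 3 probe sets of *Lef1*, a transcription factor of the Wnt pathway, with a difference of 1.02 (limma adjusted p = 0.0463), whereas the brightest *Lef1* probe set gave 0.76 (SE 0.197) and did not pass. Another probe set that passed carries several gene symbols and is not named. The count of genes changed when single arrays were left out, which also lowers the power of the test. It was 0 without stimulated replicate 2 (limma, with 597 genes at an unadjusted p under 0.05) and 0 without non-stimulated replicate 2 (585 genes). It was 1 without stimulated replicate 1 and 2 without non-stimulated replicate 3. It was 7 without stimulated replicate 3, of which 3 were among the 8 genes, and 11 without non-stimulated replicate 1, of which 4 were. *Axl*, *Igfbp2*, *Stat3* and *LOC100910286* were lost in both of these fits. Over all alternatives the fitted difference ranged from 0.97 to 1.07 for *Lgals1*, from 0.86 to 0.94 for *Axl*, from 0.77 to 0.86 for *Stat3* and from 0.65 to 1.06 for *LOC100910286*. A plain test of each gene without moderation of the variance called 1 gene, *Frzb*, with 815 at an unadjusted p under 0.05. *Hmox1* was not called under quantile normalization, and *Stat3* not under median centring or with the replicate number as a block (limma adjusted p = 0.0537). *LOC100910286* was not tested when probe sets below the median of the mean signal were left out, since its own were among those removed. Neither *Stat3* nor *LOC100910286* was called with an intensity trend or with the mean of a gene's probe sets. *Axl* was also lost when the most variable probe set stood for each gene.

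In the coordinates of the authors' deposited table, whose genome build is not given in the sources used here, *Hmox1* lies on chromosome 19 from 25622553 to 25629377 and the *Frzb* probe set on chromosome 3 from 74196165 to 74197313. *Nptx1* lies on chromosome 10 from 108286693 to 108295944, and *Stat3* on the same chromosome from 88585885 to 88612002. *Igfbp2* is placed on chromosome 15 from 36998203 to 36999965, *Lgals1* on chromosome 7 from 120144860 to 120147981, the *Axl* probe set on chromosome 1 from 83810654 to 83812352, and *LOC100910286* on chromosome 3 from 129054327 to 129109884. The table of gene names has *Igfbp2* on chromosome 9 instead, so its deposited interval is uncertain, and has the 6 other called genes it lists on the chromosomes given here. The deposited table does not give exons or introns for these intervals.

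Among the genes chosen beforehand as markers of neural differentiation, none passed the adjusted threshold. *Dcx*, which encodes the migrating-neuron protein doublecortin, differed by 0.67 (SE 0.502), and by 0.20 in its other probe set. Its brighter signal was 7.24, 7.29 and 6.05 in the stimulated arrays and 7.33, 5.56 and 5.69 in the non-stimulated arrays. *Tubb3* and *Map2*, which encode neuronal cytoskeletal proteins, differed by 0.23 (SE 0.131) and 0.088 (SE 0.257), where their other probe sets gave 0.0056 and 0.37. The neuronal transcription factor gene *Neurod1* differed by 0.25 (SE 0.199). *Gfap*, the intermediate filament of astrocytes, differed by 1.46 (SE 0.681), with values from 7.63 to 10.1 in stimulated and from 6.10 to 8.01 in non-stimulated arrays. *Nes* and *Sox2*, markers of neural stem cells, differed by 0.37 (SE 0.134) and 0.18 (SE 0.129). The proliferation marker *Mki67* differed by 0.49 (SE 0.323), the Wnt target *Axin2* by 0.040 (SE 0.10) and the oligodendrocyte lineage factor *Olig2* by -0.18 (SE 0.127), where its other probe set gave 0.031. *Fos* had no probe set of its own and is not reported.

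Of 22 gene lists fixed before the data were examined, 7 passed adjusted p 0.05 in limma's camera test with a preset inter-gene correlation, all towards higher expression in stimulated cells. The call of each was lost when the correlation was estimated from the data, and none passed fry, limma's rotation test of each list on its own (camera with an estimated correlation and fry gave 2 and 4 lists at an unadjusted p under 0.05). No member of these 7 lists passed over all genes. The arrays also stood apart in a way that crossed the groups, which bears on several lists and is given beside each. On the first principal component, with 53.5% of the variance, stimulated replicates 1 and 2 and non-stimulated replicate 1 had scores of 37.7, 18.9 and 17.3, whereas stimulated replicate 3 and non-stimulated replicates 2 and 3 had -19.9, -24.1 and -29.9.

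**Figure D2:**
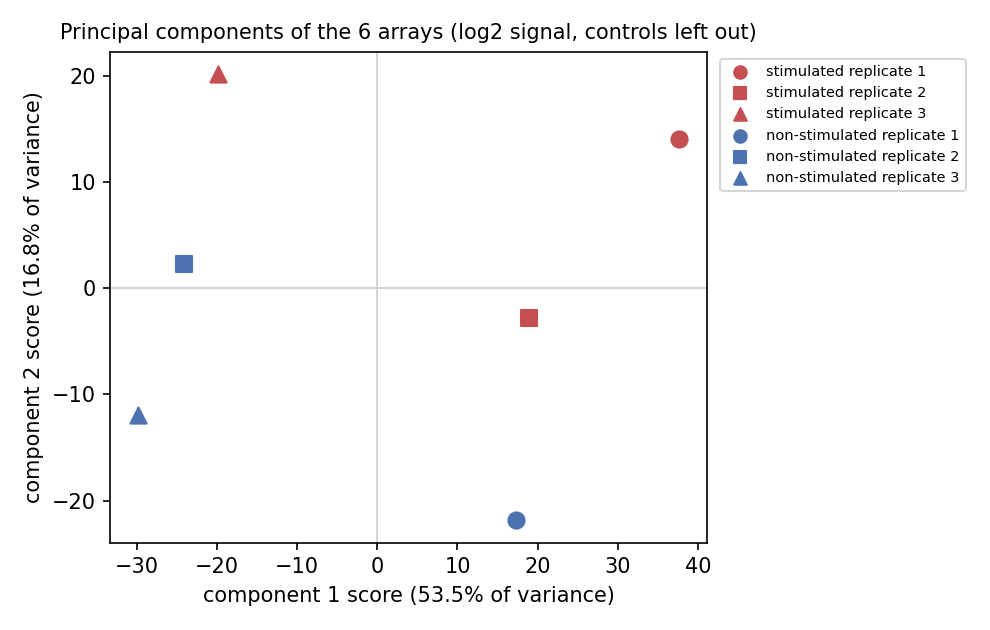
Scores of the 6 arrays on the first and second principal components of log2 signal, with the share of variance on each axis, red points for stimulated and blue points for non-stimulated arrays and a marker shape per replicate number. Non-stimulated replicate 1 lies at 17.3 on the first component, on the side of stimulated replicates 1 and 2, and stimulated replicate 3 at -19.9 lies with the remaining non-stimulated arrays.

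Cell cycle genes were higher in stimulated cells as a group. The fitted difference was positive in 23 of 24 measured members, with a median of 0.34 (adjusted p = 5.18e-09 with the preset correlation, and adjusted p = 0.672 with an estimated correlation). *Ccne1*, which encodes cyclin E1, differed by 0.52 (SE 0.256) and *Mki67* by 0.49, neither past the threshold. The list median relative to the mean of the non-stimulated arrays was 0.38, 0.46 and 0.14 in stimulated replicates 1 to 3 and 0.30, -0.14 and -0.20 in non-stimulated replicates 1 to 3, so that non-stimulated replicate 1 exceeded stimulated replicate 3.

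Genes of neural stem and radial glial cells were also fitted higher as a group, in 13 of 16 members, with a median of 0.21. The camera adjusted p was 0.000379 with the preset correlation and 0.381 with an estimated correlation. Adjusted over the list alone, 3 members passed, namely *Vim*, *Id1* and *Id4*, against 0 over all genes tested. *Id1*, an inhibitor of differentiation factors, differed by 1.08 (SE 0.203), and *Vim*, which encodes the intermediate filament vimentin, by 0.78 (SE 0.207). Per array, the median of this list was 0.23, 0.27 and 0.21 in stimulated and 0.051, 0.065 and -0.094 in non-stimulated cells. Without the 2 arrays on the far side of the component the list did not pass (adjusted p = 0.0533).

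Genes of neuronal structure and differentiation passed with 15 of 19 fitted higher and a median of 0.14 (adjusted p = 0.0137 with the preset correlation, and adjusted p = 0.790 with an estimated correlation). *Stmn3*, a member of the stathmin family, differed by 0.71 (SE 0.305) and *Dcx* by 0.67. Neuronal genes had a median of 0.22, 0.16 and 0.037 in the stimulated arrays and 0.24, -0.087 and -0.12 in the non-stimulated arrays, with the highest value in non-stimulated replicate 1. The call ended without stimulated replicate 2 (adjusted p = 0.0649), without non-stimulated replicate 2 (adjusted p = 0.0768) and without non-stimulated replicate 3 (adjusted p = 0.0699). It also ended with the mean of a gene's probe sets (adjusted p = 0.0656) and with the most variable probe set (adjusted p = 0.0785).

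Hypoxia and glycolysis genes passed with 14 of 20 fitted higher and a median of 0.17 (adjusted p = 0.00872 with the preset correlation, and adjusted p = 0.381 with an estimated correlation). The members with the widest differences went opposite ways: *Pfkp*, a phosphofructokinase gene, at 0.59 (SE 0.210) and *P4ha1*, a prolyl hydroxylase subunit of collagen synthesis, at -0.57 (SE 0.209). Hypoxia genes had a median of 0.22, 0.24 and 0.048 in the stimulated arrays and -0.0043, 0.0038 and 0.034 in the non-stimulated arrays. Without non-stimulated replicate 1 the list did not pass (adjusted p = 0.352), nor without that array and stimulated replicate 3 (adjusted p = 0.219).

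Interferon response genes passed with 13 of 18 fitted higher and a median of 0.16 (adjusted p = 0.0198 with the preset correlation, and adjusted p = 0.672 with an estimated correlation). *Ifitm3*, an interferon-induced membrane protein gene, differed by 0.94 (SE 0.235) and *Oasl* by 0.40 (SE 0.141). Interferon genes had a median of 0.051, 0.077 and 0.16 in the stimulated arrays and -0.19, 0.15 and 0.0015 in the non-stimulated arrays. The call ended without stimulated replicate 3 (adjusted p = 0.253) and without non-stimulated replicate 1 (adjusted p = 0.492), and also when the dimmer probe sets, below the median of the mean signal, were left out (adjusted p = 0.583), with array weights (adjusted p = 0.289) and without both of these arrays (adjusted p = 0.993).

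All 13 measured genes of cytosolic ribosomal proteins were fitted higher, by a median of 0.10 (adjusted p = 0.0239 with the preset correlation, and adjusted p = 0.790 with an estimated correlation). Ribosomal genes had a median of 0.15, 0.15 and 0.026 in the stimulated arrays and 0.022, -0.022 and 0.025 in the non-stimulated arrays. Activity-regulated immediate early genes, which neurons induce on depolarisation, passed with 17 of 19 fitted higher and a median of 0.079 (adjusted p = 0.0449 with the preset correlation, and adjusted p = 0.413 with an estimated correlation). *Jun* differed by 0.54 (SE 0.191) and *Ier2* by 0.49 (SE 0.183). Immediate early genes had a median of 0.17, 0.065 and 0.085 in the stimulated arrays and -0.0088, 0.078 and 0.013 in the non-stimulated arrays. Calls of both lists ended without non-stimulated replicate 1 (adjusted p = 0.167 for the ribosomal list and adjusted p = 0.460 for the immediate early list) and under quantile normalization (adjusted p = 0.168 and adjusted p = 0.0660). The ribosomal call ended also without stimulated replicate 1 (adjusted p = 0.0520), stimulated replicate 2 (adjusted p = 0.135) or non-stimulated replicate 2 (adjusted p = 0.0768), and the immediate early call without stimulated replicate 3 (adjusted p = 0.203) or non-stimulated replicate 3 (adjusted p = 0.0679). Both calls ended with the most variable probe set (adjusted p = 0.0778 and adjusted p = 0.101) and with the replicate number as a block (adjusted p = 0.0648 and adjusted p = 0.0559). They ended also without stimulated replicate 3 and non-stimulated replicate 1 together (adjusted p = 0.127 and adjusted p = 0.536) and with a residual component as a covariate (adjusted p = 0.0504 for each). The immediate early call ended further without the dimmest probe sets, a smaller share than above (adjusted p = 0.0539), with an intensity trend (adjusted p = 0.0526), with array weights (adjusted p = 0.289) and with the mean of a gene's probe sets (adjusted p = 0.0781).

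**Figure D3:**
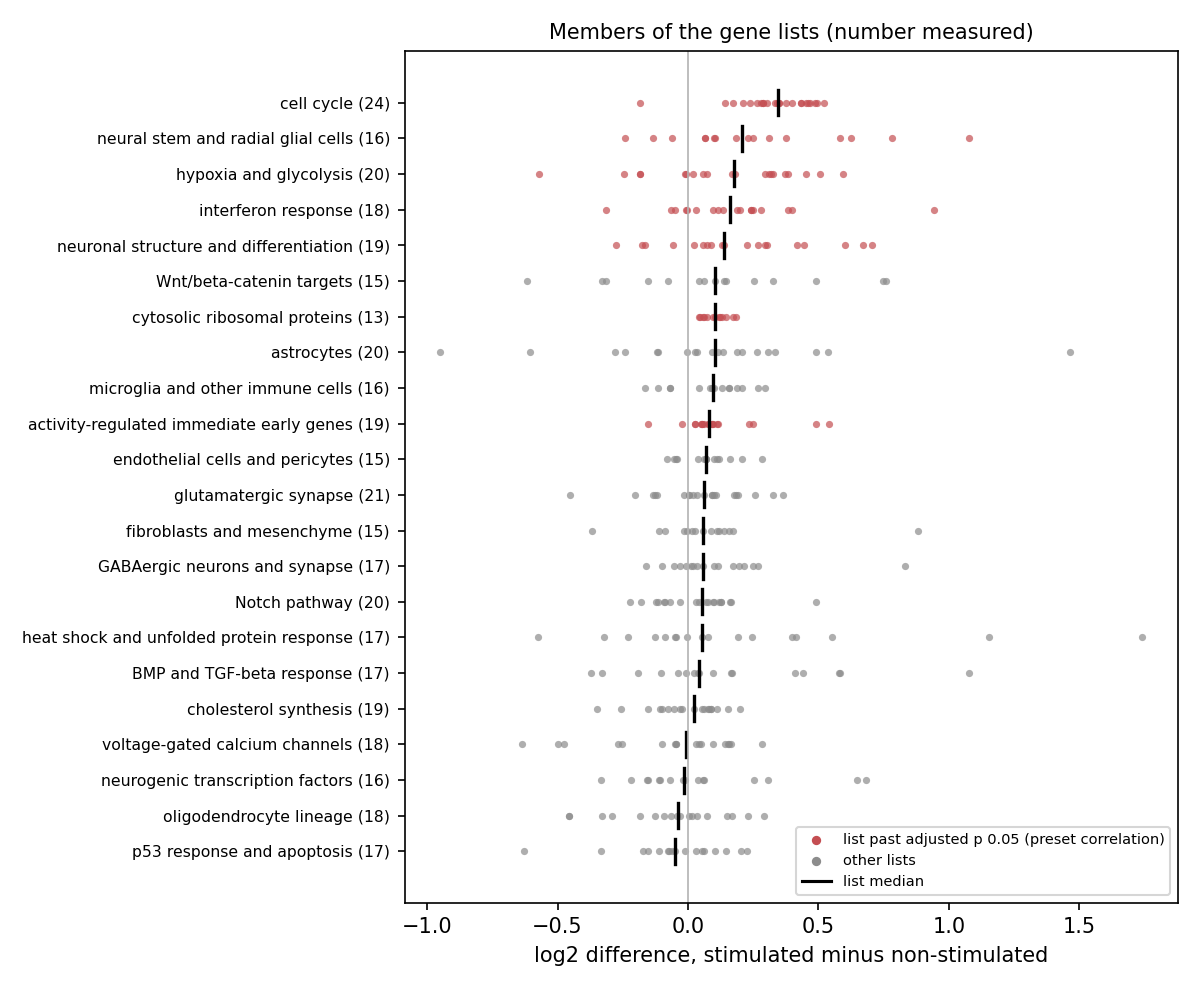
Log2 difference, stimulated minus non-stimulated (horizontal axis), of each measured member (point) of the 22 gene lists, with the list median as a black tick and the number measured in brackets. Red lists passed adjusted p 0.05 with the preset correlation; the cell cycle list has a median of 0.34 with 23 of 24 members above 0.

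Heat shock and unfolded protein response genes did not pass as a list, with a median of 0.054 over 17 measured members. The camera adjusted p was 0.0989 with the preset correlation and 0.790 with an estimated correlation. *Hmox1* was the member that rose over all genes tested, and 2 members passed when adjusted over the list alone, *Hmox1* and *Asns*, which encodes asparagine synthetase. With the preset correlation, the list passed when any of 4 arrays was left out. These were stimulated replicate 1 (adjusted p = 0.00715), stimulated replicate 2 (adjusted p = 0.0204), non-stimulated replicate 2 (adjusted p = 0.00779) and non-stimulated replicate 3 (adjusted p = 0.00953). Each of these fits kept stimulated replicate 3 and non-stimulated replicate 1, where the list median was 0.43 and -0.19. It was 0.020 and -0.090 in stimulated replicates 1 and 2, and 0.12 and 0.098 in non-stimulated replicates 2 and 3. Genes of the p53 response and apoptosis had a median of -0.049 (adjusted p = 0.553), with *Phlda3* at -0.63 (SE 0.420) and *Gadd45a* at -0.33 (SE 0.179). Cholesterol synthesis genes had a median of 0.024 with a mean of -0.012, and the test pointed lower (adjusted p = 0.458). *Sc5d* differed by -0.35 (SE 0.116) and *Msmo1* by -0.26 (SE 0.150).

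Lists of neuronal function did not pass. Neurogenic transcription factors had a median of -0.017 while the mean and the test pointed higher (adjusted p = 0.910), with *Sox11* at 0.65 (SE 0.207). Voltage-gated calcium channel genes had a median of -0.0066 (adjusted p = 0.458). *Cacnb4* stood at -0.63 (SE 0.191), where its other probe sets gave -0.17 and -0.24, and *Cacna2d1* stood at -0.50 (SE 0.306), where its other probe set gave -0.034. Glutamatergic synapse genes had a median of 0.062 (adjusted p = 0.458), with *Gria4* at -0.45 (SE 0.163) and *Camk2b* at 0.36 (SE 0.121). The other *Gria4* probe sets gave -0.48 and 0.045. Genes of GABAergic neurons and synapses had a median of 0.056 (adjusted p = 0.174), with *Reln* at 0.83 (SE 0.320) and *Slc32a1* at 0.27 (SE 0.155).

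Signalling lists did not pass either. Wnt/beta-catenin targets had a median of 0.11 (adjusted p = 0.504), with *Lef1* at 0.76 and *Myc* at 0.75 (SE 0.382). Notch pathway genes had a median of 0.055 (adjusted p = 0.661), with *Notch1* at 0.49 (SE 0.175) and *Numb* at -0.22 (SE 0.131), where the other *Numb* probe set gave 0.089. Genes of the BMP and TGF-beta response had a median of 0.043 (adjusted p = 0.174), with *Id1* at 1.08 and *Id3* at 0.58 (SE 0.210). Adjusted over the list alone, *Id1* passed, against no member over all genes tested. This list passed with the mean of a gene's probe sets (adjusted p = 0.0428) and with the most variable probe set (adjusted p = 0.0110).

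No list of markers of other cell types passed. Astrocyte genes had a median of 0.10 (adjusted p = 0.458), with *Gfap* at 1.46 and *Slc4a4* at -0.95 (SE 0.366), where the other *Slc4a4* probe set gave -0.096. The astrocyte list median was 0.33 in stimulated replicate 3 and -0.35 in non-stimulated replicate 1, the 2 arrays on the far side of the first component from the rest of their groups. Without these 2 arrays the astrocyte list turned lower and passed, from a mean of 0.094 to -0.32 (adjusted p = 0.0318 with the preset correlation). The groups left are the sides of the component, which the astrocyte medians separate. The reversal therefore follows from how the arrays were picked and is no evidence of a fall. The mean of the list was also below 0, without passing, with array weights or without either array alone. Oligodendrocyte lineage genes had a median of -0.037 (adjusted p = 0.227), with *Ugt8* at -0.46 (SE 0.264; other probe set -0.020) and *Tspan2* at -0.45 (SE 0.169), and the list passed without non-stimulated replicate 2 (mean -0.17, adjusted p = 0.00342). Genes of microglia and other immune cells had a median of 0.096 (adjusted p = 0.421), with *Cd53* at 0.30 (SE 0.226) and *Aif1* at 0.27 (SE 0.178, other probe set -0.019). That list passed without stimulated replicate 2 (adjusted p = 0.0422 with the preset correlation). Its median was 0.38 in stimulated replicate 1, against -0.0061 and -0.054 in stimulated replicates 2 and 3, so the pass rests on 1 array. Endothelial and pericyte genes had a median of 0.068 (adjusted p = 0.458), with *Kcnj8* at 0.28 (SE 0.189) and *Kdr* at 0.21 (SE 0.262; other probe set -0.029). Genes of fibroblasts and mesenchyme had a median of 0.058 (adjusted p = 0.553), with *Postn* at 0.88 (SE 0.567) and *Col5a1* at -0.37 (SE 0.223).

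The authors' deposited table gives its own comparison of the same arrays. Of its 31042 probe sets, 1 had an FDR p under 0.05, the *Frzb* probe set that represents the gene here. An unadjusted p under 0.05 was reached by 1540 probe sets in the authors' deposited table, where 5 percent of the probe sets is 1552. The authors' deposited table lists 469 probe sets at least 1.5-fold higher and 790 at least 1.5-fold lower in stimulated cells, of which 122 and 81 also had an unadjusted p under 0.05. Term enrichments in the authors' deposited table rest on probe sets chosen on these same arrays by fold and unadjusted p, and so are not independent evidence of a direction. For the higher probe sets, 23 of 250 terms had a Benjamini p under 0.05. They include calcium ion binding with 14 genes (Benjamini p 0.00167 in the authors' deposited table), among them *Anxa2*, *S100a4* and *Syt1*, and extracellular matrix with 9 genes (Benjamini p 0.0034 in the authors' deposited table), among them *Lgals1*, *Vim* and *Emilin1*. For the lower probe sets, 0 of 31 terms in the authors' deposited table had a Benjamini p under 0.05.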

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

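Every test in this part was chosen after the result it bears on had been seen, except the test of the oxidative-stress and xenobiotic list, whose members' values had not been seen when it was set, and its comparison with other splits and the test without members named in the deposited terms were added afterwards. The bound for each test set afterwards was also chosen with the values in view.

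2 control transcripts that enter no comparison were higher in every stimulated than in every non-stimulated array. The probe sets of the added control transcript thr averaged 6.85 ± 0.27 (SD, n = 3) in stimulated and 6.41 ± 0.12 (SD, n = 3) in non-stimulated arrays, a difference of 0.439, whereas the controls dap, lys and phe differed by -0.067, -0.117 and -0.16. The control trpn differed by 0.0456, at signals of 2.79 ± 0.039 and 2.75 ± 0.015 near the lower end of the scale.

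The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The labelled split called 8 genes, 8 genes at least 1.5-fold apart and 9 probe sets. In each of these counts 2 of the 10 splits reached as many, the labelled one included, and the highest of the others were 1776 genes, 684 genes at least 1.5-fold apart and 2817 probe sets. All 3 highest counts came from the split of stimulated replicates 1 and 2 with non-stimulated replicate 1 against the rest, which points to a structure of the samples. For gene lists the labelled split called 7, the highest other split called 8, and 3 of the 10 splits reached at least 7.

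The first pattern is that structure, the place of stimulated replicate 3 and non-stimulated replicate 1 among the arrays of the other group. In both groups the first component fell from replicate 1 to 3. Scores were 37.7, 18.9 and -19.9 in stimulated and 17.3, -24.1 and -29.9 in non-stimulated arrays. At each replicate number the stimulated array scored higher. Deviations of same-numbered arrays from their group means correlated at 0.48, -0.45 and 0.58 for replicates 1 to 3. Whether a difference shared by same-numbered samples places these arrays therefore stays open. An exchange of the labels of stimulated replicate 3 and non-stimulated replicate 1 would make the labelled split one of the mixed splits. The labelled split called 8 genes (limma, with 940 genes at an unadjusted p under 0.05). The 8 splits that follow neither the labels nor the component all called 0 genes (91 to 744 genes). This argues only weakly against an exchange, since the count of the labelled split was known when the bound was set. RNA quality stays open, since the gap between the sides was 0.0459 in the difference between the 3' and 5' beta-actin controls, but -0.0223, an overlap, for GAPDH. Cell content stays open, as 4 of 8 cell type lists passed adjusted p 0.05 in the gene loadings of the component (limma's cameraPR with the preset correlation) but 0 with an estimated correlation, neuronal, oligodendrocyte and microglial genes towards stimulated replicate 1 and astrocyte genes at the opposite end, beside cell cycle genes with 24 of 24 members towards stimulated replicate 1. Heat shock and unfolded protein response genes also lay at that opposite end, with 4 of 17 members towards stimulated replicate 1. Their limma adjusted p was 0.0113 with the preset correlation and 0.511 with an estimated one, so that a difference in stress or culture state stays open too. By array, the medians of the neuronal, oligodendrocyte and astrocyte lists separated the sides. The microglial median did not. It was 0.38 in stimulated replicate 1, against -0.0061 in stimulated replicate 2 and 0.034 in non-stimulated replicate 1. The hybridisation controls bioB, bioC, bioD and cre averaged 9.56 in stimulated replicate 1, against 9.90 to 10.16 in the other arrays. A technical cause was not tested.

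The second pattern is that fold changes in the authors' deposited table differ from those of plain means, in both directions. In the authors' deposited table, 1259 probe sets differ by at least 1.5-fold and 822 of them do not with plain means of the same 3 arrays, while 65 of 502 that do with plain means do not there. Bi-weight averaging, which gives less weight to values far from the median, returned both deposited averages within 0.01 for 100% of probe sets, and plain means did so for 10.7%. Among the 822, stimulated replicate 3 had weight 0 in 357 and non-stimulated replicate 1 in 495, against 4 to 16 for each other array. The authors' deposited table gives a fold of 3.11 for *Dcx*, 1.6 for *Gfap* and 1.13 for *Postn*, where plain means gave 1.59, 2.76 and 1.84, so the averaging accounts for larger and smaller folds alike, and no biological explanation was tested.

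The third pattern is the high signal of *Hmox1*, *Nqo1* and *Cyp1a1*, genes of the response to oxidative stress and foreign compounds, in stimulated arrays. *Nqo1* (log2 difference 1.91, limma adjusted p = 0.0723) and *Cyp1a1* (1.96, limma adjusted p = 0.0781) missed the threshold in the fit without a block, lay higher in 3 of 3 stimulated arrays and were chosen after their values were seen. A list of further genes of this response, which leaves out the members already seen, had 20 of 21 measured members fitted higher and a median of 0.332 (fry p = 0.000374, and with camera at an estimated correlation p = 0.00173, 1 of 2 lists tested in this way), while no other split reached a median beyond 0.20; without 4 members that the authors' deposited terms name as higher on these arrays, 16 of 17 were higher with a median of 0.248, past 0.05 in fry, against at most 0.132 in other splits. Structure along the first component is argued against as the whole cause, since with the array scores as a covariate the median was 0.389, or 0.308 without those 4, each past 0.05 in fry, and 18 of 21 members were higher in stimulated replicate 3 than in non-stimulated replicate 1. A response to oxidative stress or xenobiotics may therefore accompany stimulation, as a hypothesis, and whether light itself, the opsin's activity or handling would give it stays open, since light without an opsin was not analysed here.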

How the results depend on the processing

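The alternatives without both arrays that stand apart and with a residual component were chosen after seeing the data. With 8 genes, 8 genes at least 1.5-fold apart, 9 probe sets and 7 lists in the fit as reported, array weights gave 1220, 510 and 948 of the first 3 counts, the 2 arrays left out together gave 1411, 1019, 2249 and 3 lists, and the first residual component as a covariate gave 409, 213 and 603. All 8 genes were shared with each of these 3 settings. The arrays left out were picked by their place on the first component, and the residual component is drawn from the same spread it removes and cannot change a difference, so the counts under these 2 settings are no evidence of more changed genes. Array weights gave stimulated replicate 2 a weight of 7.27 against 0.445 to 1.24 for the others, and the cause of the higher count there was not tested. Without stimulated replicate 3 and non-stimulated replicate 1 the astrocyte list reversed, from a mean of 0.094 to -0.32 (adjusted p = 0.0318 with the preset correlation). The groups left are the sides of the first component, so this reversal is no evidence of a fall either. Whether the replicate numbers pair the samples cannot be told from these arrays. The correlations of same-numbered deviations were 0.48, -0.45 and 0.58 for replicates 1 to 3, and those of unlike numbers ran from -0.69 to 0.44. The replicate block gave 15 genes, 15 genes at least 1.5-fold apart and 68 probe sets, without *Stat3* and with *Cyp1a1* (limma adjusted p = 0.00402), *Vwc2* (0.0334), *Nqo1* (0.0341), *Anxa2* and *Emp3* (0.0462 each) among those added, and its 5 lists left out the immediate early (adjusted p = 0.0559) and ribosomal lists (adjusted p = 0.0648). Quantile normalization left 2 probe sets and leaving out the lower part of the probe sets by mean left 5. Leaving out each array in turn gave 0 to 11 genes, 0 to 11 genes at least 1.5-fold apart, 0 to 11 probe sets and 3 to 7 lists. The authors' deposited averages and p-values gave 1, 1 and 1, as did the plain test, 1, 1 and 1. A test against 1.5-fold left 2 genes. An adjusted p of 0.1 gave 19 and 19 genes, and 0.01 gave 2 and 2. Camera with an estimated correlation and fry each called 0 lists (limma, 2 and 4 at an unadjusted p under 0.05). Where no reason is given, the cause was not tested.

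Single named genes and lists gave 1414 values under the alternatives, of which 1238 kept their side of the threshold without a reversed call, 103 lost the call, 72 gained one and 1 reversed. Among the 1238, 39 changed sign without being called in either fit. *Frzb* kept its call in 16 of 18 alternatives, *Nptx1* in 14, *Hmox1* and *Lgals1* in 12, *Igfbp2* in 11, *Axl* in 10, *Stat3* in 6 and *LOC100910286* in 7 of 17. These tallies include array weights, the fit without both arrays that stand apart and the residual component. All 8 genes were called there, among 1220, 1411 and 409 genes. Calls kept in these settings add no support. The log2 difference stayed between 1.34 and 1.48 for *Frzb*, between 1.6 and 1.93 for *Hmox1* and between -2.28 and -1.97 for *Nptx1*. The pseudocount alternative was not run. Signals near the lower end of the scale limit what could be seen for dim genes.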

Other observations

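The genes in the next paragraph were chosen after their values were seen. The test of the STAT3 target list was set before the values of its members were seen, and its comparison with other splits was added afterwards.

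At an adjusted p under 0.1, 19 genes differed, 18 higher and 1 lower in stimulated cells. All 19 had groups that do not overlap, which selection by p makes likely and which adds no support. Beyond the 8 genes past 0.05 they include *Emp1* (log2 difference 1.0, SE 0.129) and *Emp3* (1.11, SE 0.141), which encode membrane proteins of the same family, both at limma adjusted p = 0.0723. *Anxa2*, a calcium-dependent phospholipid-binding protein gene, differed by 1.05 (SE 0.134), and *Tm4sf1*, a transmembrane protein gene, by 0.74 (SE 0.0994). *Vwc2*, which encodes a secreted BMP antagonist, differed by 1.48 (SE 0.197), *Bhlhe41*, a transcriptional repressor of the circadian clock, by 1.10 (SE 0.153), and the imprinted gene *Mest* by 0.83 (SE 0.109). *Gas2* and *Emilin1*, an extracellular matrix glycoprotein gene, differed by 0.89 (SE 0.126) and 0.73 (SE 0.107). None of these passed 0.05 in the fit without a block.

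Since *Stat3* rose, genes known as STAT3 targets may be higher in stimulated cells as well. The 15 measured members, without *Stat3* and the targets already seen, had a median of 0.237, with 14 fitted higher and 0 past the threshold over all genes tested (fry p = 0.0148, and with camera at an estimated correlation p = 0.0231). *Socs3*, a feedback inhibitor of this pathway, differed by 1.29 (SE 0.264, limma adjusted p = 0.295), and 3 members, *Socs3*, *Tnfrsf1a* and *Icam1*, passed when adjusted over the list alone. The list median was 0.39, 0.15 and 0.22 in the stimulated and -0.12, 0.10 and 0.0059 in the non-stimulated arrays. Another of the 10 splits gave a median of size 0.24, so the test leaves the hypothesis open.

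Members of the oxidative-stress and xenobiotic list that passed when adjusted over the list alone were 9 of 21, against 0 over all genes tested. *Aldh3a1*, an aldehyde dehydrogenase gene, differed by 1.74 (SE 0.342), *Cyp1b1*, a target of the aryl hydrocarbon receptor, by 1.08 (SE 0.165), and *Srxn1*, which encodes sulfiredoxin, by 0.69 (SE 0.181). The glutamate-cysteine ligase subunit gene *Gclm* went the other way, at -0.20 (SE 0.205). The list median was 0.39, 0.42 and 0.35 in the stimulated and -0.15, 0.040 and -0.0043 in the non-stimulated arrays. The authors' deposited table names *Aldh3a1*, *Cyp1b1* and *Abcc4* in the term response to organic cyclic compound and *Srxn1* in the term cytoplasm, both drawn from the same arrays.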
